A study of Hordeum vulgare with 18 samples.

How the data were processed

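RNA from shoots and roots of germinated barley seeds (Hordeum vulgare, cultivar Haruna Nijo) was measured on 18 two-colour Agilent oligonucleotide arrays, each with 42483 probes of 60 bases besides the control spots. Per the labels, seeds were germinated for 4 days at 24 °C with 8 h days, 3 germinated seeds were moved to 4 °C for 3 h, 6 h or 24 h, and shoot and root were harvested separately. On every array Cy5 carried the cold-treated RNA and Cy3 carried untreated 0 h RNA of the same tissue, 400 ng each, per the labels' protocols. The groups were shoot 3 h, shoot 6 h, root 3 h and root 6 h with 4 biological replicates each, and shoot 24 h and root 24 h with 1 array each. No array had its dyes swapped, so a dye bias of a probe stays in each cold against 0 h ratio. Such a bias cancels where 2 cold groups are contrasted. The untreated plants were harvested at 0 h only, so time of day differs between the channels at 3 h and 6 h by the length of the treatment. A treatment of 24 h returns to the same time of day.

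The deposited scanner files give, for each spot, its mean intensity and the median intensity of its local background in both channels, with no normalization, and a processed intensity that was background-subtracted, detrended and dye-normalized, per the file headers. The log10 ratio of processed Cy5 over Cy3 is also in each scanner file, per the file headers, and the authors' deposited series table holds the same log10 ratios. The array medians of that table lay between -0.023 and 0. The flags for signal above background, saturation and outlier spots are the scanner software's own, per the file headers. The headers name Feature Extraction 9.5.3.1, whereas the submitters' processing notes name Agilent Feature Extraction 9.1.

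From these files, log2 ratios of Cy5 over Cy3 were computed from mean intensities with normexp background correction (offset 50) and loess within each array, in limma 3.58.1 under R 4.3.3. Control spots and spots with an outlier flag had weight 0 in the loess, and flagged values (1580 in the 16 arrays of the fit) were left out. A probe was tested if it was well above background in either channel on at least 4 of the 16 arrays of the 4 replicated groups. This kept 39503 probes and left out 2980. A model with 1 mean per group was fitted to the 16 arrays with limma's lmFit and eBayes, so that the groups shared 1 estimate of the spread per probe. Each group mean was tested against 0, 6 h was contrasted with 3 h within each tissue, and shoot was contrasted with root at each time. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the tested probes, and the threshold was an adjusted p of 0.05. Counts of probes past the threshold with a mean log2 ratio of at least 1 in size are given beside the full counts. For untreated shoot against untreated root, the Cy3 signals were taken after the same steps and quantile normalization of the average intensity (Aquantile), the 3 h and 6 h arrays of a tissue and replicate were averaged, and 4 shoot means were set against 4 root means in limma. The 24 h arrays were described without a test.

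Data were simulated for 39503 probes, 200 of them changed, as independent values with each probe's residual spread of log2 ratios. The test of shoot 6 h against 0 h recovered 54% of probes changed by 0.5 on the log2 scale. It recovered 86% of those changed by 1 and 98% of those changed by 2, with 4 false calls among 166. For shoot 6 h against 3 h the shares were 24%, 69% and 96%, with 5 false calls among 134. For the shoot and root contrast at 6 h they were 20%, 69% and 94%, with 0 false calls among 126. For untreated shoot against root they were 12%, 65% and 92%, with 11 false calls among 128. That simulation also used the spread of the log2 ratios and not that of the Cy3 signals. The simulations left out the correlation within replicates (0.29 in the fit) and changed far fewer probes than passed in the comparisons with 0 h. The shares therefore describe the simulated setting and not the error rates of the real tests. The number of arrays limits the precision of every value.

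The replicate numbers come from the labels. Deviations from the group means correlated across probes in every pair of arrays with the same number. The correlation was 0.40 to 0.87 between the 3 h and 6 h arrays of a tissue (8 pairs) and 0.16 to 0.38 between shoot and root (8 pairs). All lay above the bound of 0.1 set beforehand, so the numbers were taken to pair the samples. Between shoot 3 h and 6 h, the same-numbered array was the best match in 3 of 4 cases, and in 4 of 4 for each other pair of groups. The pairing is part of the alternatives, and blocked counts stand beside those results that they moved by more than 1.5 times. In Cy3 alone the 3 h and 6 h arrays of a tissue correlated at 0.64 to 0.98, against 0.29 to 0.70 in Cy5. The untreated RNA of a replicate was therefore treated as shared between times, and the persistence of changes from 3 h to 6 h and to 24 h was read in replicates held out from the choice of probes. The contrasts of 6 h with 3 h and the probes named for them use every replicate for both. Arrays lay on 5 slides. The slides of replicates 2, 3 and 4 held 1 array of each of the 4 replicated groups, so a contrast within a slide has values but no test. Replicate 1 was spread over 2 slides. None of the 153 pairs of arrays had an identical channel.

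The probes carry names of cDNA clones, and the files pair them with no gene name. Of the probe and clone names, 0 matched the reference table of barley genes, and the 43 gene lists fixed before the data were examined matched 0 names. The planned tests of gene lists and of tissue markers, and the planned rule for named genes, which asked for informative gene names, could therefore not be applied. In their place, at most 2 probes that rose and 2 that fell are named per comparison, those with the largest change among probes past the threshold with the same sign in all 4 replicates. For 24 h, the probes named are those of the same tissue at 6 h and the 2 largest each way among probes well above background in both channels. For the untreated tissues, they are the 2 largest each way. The plan had set 5 each way for these groups. No genome was used, so no coordinates are given. The 60-base sequences were also read in 3 forward frames for 50 conserved protein motifs, and the classes with a match in an open frame and none on the reverse strand were kept (10 classes, 12 probes).

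Where a probe was not well above background in a channel on any array of a group, its level there is not measured. For the untreated tissues, such a signal was raised to the lowest one well above background, and the resulting bound is written as "at least". For the cold contrasts the fitted mean ratio is given, which is not a bound and is open to dye bias. A fitted difference that rests on such a ratio has no measured size. Alternatives tried were no background correction, an offset of 10, the processed signals centred on the median, the deposited log10 ratios, median centring without loess, scaling between arrays, no filter and a stricter filter on dim probes, a fit to only the arrays compared or to all 18 arrays, array weights, leaving out each array in turn, and the replicate or the slide as a block.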

Results

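The data were 18 hybridizations of cold-treated barley shoot or root RNA against untreated RNA of the same tissue. Barley is a temperate cereal that acclimates to low temperature, and the series followed the transcript levels of 4-day-old seedlings after 3 h, 6 h and 24 h at 4 °C. The 3 h and 6 h groups held 4 biological replicates per tissue and the 24 h groups held 1. Between 84.8% and 90.6% of the probes were well above background in Cy5 and between 82.0% and 89.1% in Cy3, and at most 6 probes per array were saturated. Ratios of replicate arrays correlated across probes at 0.43 to 0.83 for shoot 3 h, 0.68 to 0.88 for shoot 6 h, 0.53 to 0.80 for root 3 h and 0.63 to 0.87 for root 6 h. Probes are identified by the clone they were designed from, and values are mean log2 ratios of cold over 0 h with the SD over replicates.

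After 3 h in the cold, shoots showed a response dominated by rises among the larger changes. Of 39503 probes tested, 7361 rose and 4670 fell, and 1937 of them changed by at least 2-fold, of which 1705 rose and 232 fell. Changes of at least 4-fold comprised 339 rises and 13 falls. The largest rise was that of probe Hv1136B16_1, at 5.14 ± 0.38 (SD, n = 4; limma adjusted p = 9.9e-10). The size depended on the processing, at 5.69 with an offset of 10, 6.28 in the deposited ratios and 6.39 with the processed signals. Its sequence is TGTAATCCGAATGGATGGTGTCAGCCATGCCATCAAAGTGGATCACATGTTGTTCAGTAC, and its untreated signal was well above background on 3 of the 4 arrays. Probe Hv2030H21_2 followed at 4.82 ± 1.62 (SD, n = 4; limma adjusted p = 0.0013), with replicates between 3.15 and 6.84. The deepest fall was that of Hv3085E19_1, at -4.05 ± 1.33 (SD, n = 4; limma adjusted p = 2.7e-06), with the sequence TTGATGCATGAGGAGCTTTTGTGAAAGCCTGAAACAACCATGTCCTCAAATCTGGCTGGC. Hv1100A04_1 stood at -2.43 ± 0.51 (SD, n = 4; limma adjusted p = 2.9e-07). In a fit to the 4 shoot 3 h arrays alone 7620 probes passed the threshold, and with the processed signals 3075 probes passed it at 2-fold or more, of which 2561 rose and 514 fell. In the deposited ratios, which are not centred, 5921 rose and 7705 fell, with 2167 rises and 656 falls at 2-fold or more.

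After 6 h the shoot response was broader. In all, 10374 probes rose and 8682 fell, which is 48.2% of those tested, and 2865 rises and 689 falls reached 2-fold. Rises of at least 8-fold numbered 193, against 2 falls. Hv1136B16_1 rose to 6.36 ± 0.24 (SD, n = 4; limma adjusted p = 5.6e-11), and stood at 6.87 with an offset of 10, 7.18 in the deposited ratios and 7.28 with the processed signals. Hv2050M07_1 stood at 6.20 ± 0.70 (SD, n = 4; limma adjusted p = 9.1e-07). Its sequence is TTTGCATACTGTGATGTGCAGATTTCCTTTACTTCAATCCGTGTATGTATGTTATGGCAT. Hv3085E19_1 again fell furthest, to -4.71 ± 0.52 (SD, n = 4; limma adjusted p = 2.1e-07), followed by Hv2106P13_2 at -3.01 ± 0.53 (SD, n = 4; limma adjusted p = 9.2e-07). The deposited ratios without centring gave 8229 rises and 12451 falls, and 3405 rises and 1745 falls at 2-fold or more.

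**Figure D1:**
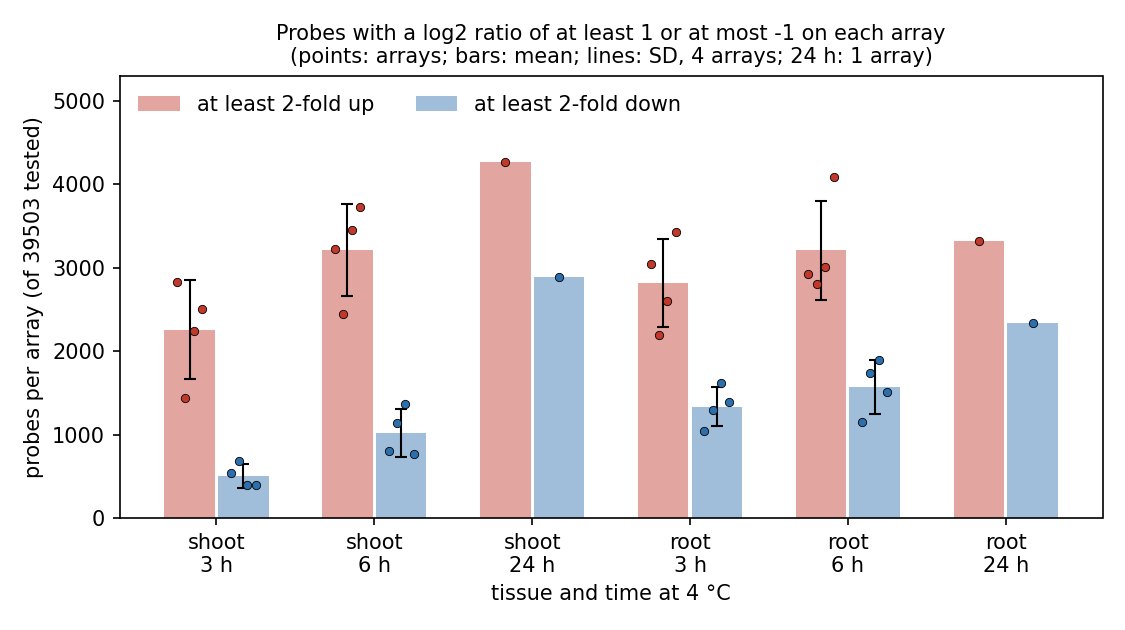
Number of probes with a log2 ratio of at least 1 (red) or at most -1 (blue) on each array, by tissue and time at 4 °C; points are arrays, bars are means and lines are the SD of 4 arrays, with 1 array at 24 h. Shoot arrays at 3 h held between 397 and 688 such falls and between 1444 and 2832 rises, and the 24 h shoot array held 2894 falls and 4273 rises.

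Roots responded at 3 h with 8809 rises and 7982 falls, of which 2420 rises and 736 falls reached 2-fold. Both probes of clone Hv2030H21 rose most, at 6.10 ± 2.09 for Hv2030H21_2 (SD, n = 4; limma adjusted p = 0.00013) and 6.03 ± 2.00 for Hv2030H21_1 (SD, n = 4; limma adjusted p = 0.00018). Their sequences overlap, and their replicates spread widely, from 3.19 to 7.63 for Hv2030H21_2. The sequence of this probe is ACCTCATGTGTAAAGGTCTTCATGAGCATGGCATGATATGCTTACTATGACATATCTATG. Hv3085E19_1 fell in root as it did in shoot, to -3.06 ± 0.62 (SD, n = 4; limma adjusted p = 1.8e-05). Hv2052F11_1 reached -2.99 ± 2.17 (SD, n = 4; limma adjusted p = 0.0025), but it no longer passed in a fit to the 4 root 3 h arrays alone (adjusted p = 0.053, with a range of 0.00067 to 0.053 over the alternatives). The deposited ratios gave 7215 rises and 10725 falls in all, and 2826 rises and 1805 falls at 2-fold or more. With the processed signals, 3102 rises and 1551 falls reached 2-fold.

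At 6 h, 10272 root probes rose and 9288 fell, and 2816 rises and 1055 falls reached 2-fold. The probes Hv2030H21_2 and Hv2030H21_1 stood at 5.86 ± 2.30 (SD, n = 4; limma adjusted p = 0.00012) and 5.80 ± 2.23 (SD, n = 4; limma adjusted p = 0.00017). Hv3085E19_1 had fallen to -3.79 ± 0.43 (SD, n = 4; limma adjusted p = 1.4e-06) and Hv2050M16_1 to -3.30 ± 0.46 (SD, n = 4; limma adjusted p = 1.4e-08). The deposited ratios gave 8680 rises and 11919 falls, and 3359 rises and 2272 falls at 2-fold or more. Where a clone was represented by 2 tested probes (5755 clones), the log2 ratios of the pair correlated across clones at 0.99 in each of the 4 comparisons with 0 h. Both probes passed the threshold for 2805 clones in root at 6 h, with the same sign for 2803 of them. The 2 probes of a clone can overlap in sequence, as those of Hv2030H21 do, and lie on the same arrays, so they are not independent measurements.

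Far fewer probes distinguished 6 h from 3 h than distinguished either time from 0 h. These counts are not alike, since a dye bias of a probe stays in the ratios to 0 h and cancels between times. The median SE was also larger, at 0.14 between times against 0.10 in the comparisons with 0 h. The gap in counts is therefore no measure of how complete the response was at 3 h. In shoot 577 probes differed, 380 of them higher at 6 h, and 181 differed by at least 2-fold. The replicate block raised these counts to 1780 and 332. Hv1092H07_2 stood at 5.87 ± 0.18 at 6 h (SD, n = 4; limma adjusted p of the fitted difference = 0.00043) and at a fitted 3.03 at 3 h. Hv1110O16_1 stood at 4.67 ± 0.24 at 6 h (SD, n = 4; limma adjusted p = 0.00045) and at a fitted 1.84 at 3 h. The untreated signal of these 2 probes was not well above background on any shoot 3 h array. Their 3 h ratios, and with them the size of the difference, are therefore not measured. A 3 h ratio as high as that at 6 h is not excluded by these ratios alone. Neither difference passed with the processed signals, and over all alternatives the adjusted p in limma ranged from 4.8e-05 to 0.12 and from 6.9e-05 to 0.13. Hv1100C09_1 was above its 0 h level at 3 h, at 1.21 ± 0.70, and stood at -0.91 ± 0.75 at 6 h (SD, n = 4; limma adjusted p of the difference = 0.021). Hv2032H17_1 went from 1.57 ± 0.51 to -0.14 ± 0.42 (SD, n = 4; limma adjusted p = 0.0045). Neither of these differences passed in a fit to the 8 shoot arrays alone, and over the alternatives the adjusted p in limma ranged from 0.0064 to 0.087 and from 0.00049 to 0.052. The call of Hv1100C09_1 was also lost without shoot 3 h replicate 1 (adjusted p = 0.053) or 3 (0.051) and without shoot 6 h replicate 2 (0.052), 3 (0.083) or 4 (0.051). The count of 577 fell to 347 without shoot 3 h replicate 1, to 361 without shoot 3 h replicate 3 and to 179 without shoot 6 h replicate 3, which left 81 at 2-fold or more. With scaling between arrays 100 probes were higher and 26 lower at 6 h, and the processed signals gave 246 higher and 243 lower.

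In root 125 probes differed between 6 h and 3 h, 86 of them higher at 6 h, and 33 differed by at least 2-fold. With the replicate block 824 differed, 91 of them by at least 2-fold. In a fit to the 8 root arrays alone, 0 passed the threshold in limma and 4203 had an unadjusted p under 0.05. Hv3135G05_1 went from 0.38 ± 0.27 at 3 h to 2.07 ± 0.33 at 6 h (SD, n = 4; limma adjusted p = 0.0016). Hv1129B03_1 went from -0.04 ± 0.76 to 1.53 ± 0.35 (SD, n = 4; limma adjusted p = 0.045). Hv1100C09_1 showed the course it had in shoot, from 1.57 ± 0.50 to -0.59 ± 0.58 (SD, n = 4; limma adjusted p = 0.046), and Hv3129N03_1 went from 2.22 ± 0.47 to 0.45 ± 0.51 (SD, n = 4; limma adjusted p = 0.0099). None of these 4 differences passed in the fit to the 8 root arrays, and the highest adjusted p over the alternatives was 0.14, 0.21, 0.16 and 0.20 in the same order. The count of 125 rose to 211 without root 3 h replicate 1. It fell to 11 without root 3 h replicate 2, to 11 without root 3 h replicate 3, to 17, 16 and 31 without root 6 h replicates 2, 3 and 4, and at 2-fold or more these 6 fits gave 57, 6, 3, 8, 6 and 14. Each of the last 5 fits also ended the calls of Hv1129B03_1 (adjusted p between 0.10 and 0.15) and Hv1100C09_1 (between 0.11 and 0.16), and the fit without root 3 h replicate 1 ended that of Hv1100C09_1 (0.056).

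Most early changes in both tissues kept their direction at 6 h in replicates that had no part in their choice. The 1017 shoot probes at least 2-fold up at 3 h in replicates 1 and 2 had median log2 ratios of 1.61 and 1.78 at 3 h in replicates 3 and 4, and of 1.99 and 2.25 at 6 h. The 1501 chosen in replicates 3 and 4 had medians of 1.51 and 1.10 at 3 h in replicates 1 and 2, and of 1.84 and 1.18 at 6 h. Between 86.0% and 99.5% of these probes were above 0 at 6 h in the replicates not used to choose them. The 1651 root probes chosen in replicates 1 and 2 had medians of 1.47 and 1.82 at 3 h and of 1.69 and 2.11 at 6 h in replicates 3 and 4. The 1892 chosen in replicates 3 and 4 went from medians of 1.54 and 1.34 to 1.40 and 1.15 in replicates 1 and 2. The direction of the small shift in root thus differed between replicates. Of these root rises, 86.4% to 99.9% were above 0 at 6 h. Falls chosen in the same way were below 0 at 6 h for 93.1% to 98.5% of probes in shoot and 83.4% to 94.7% in root. Every array had the same dye order, so a dye bias of a probe would persist in the same way.

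**Figure D2:**
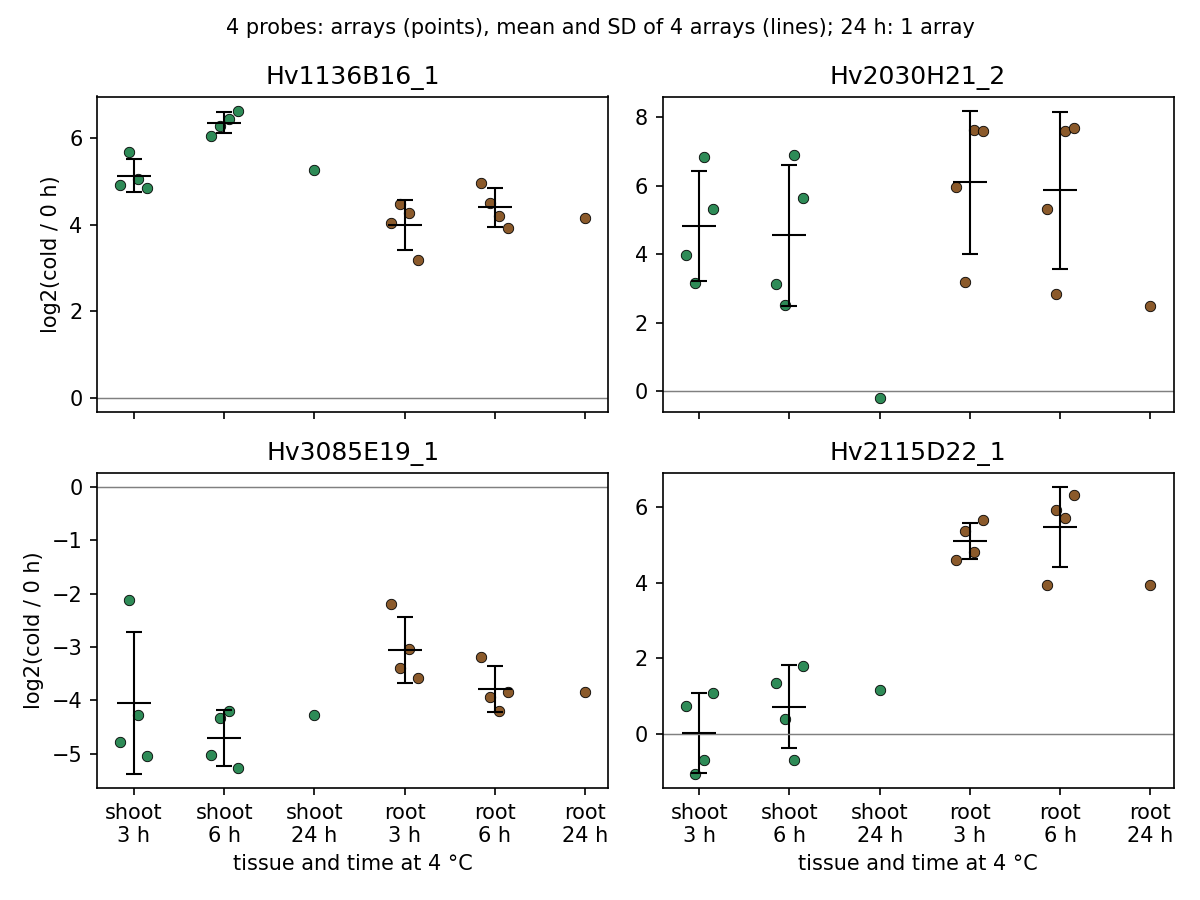
Log2 ratio of cold over 0 h for 4 named probes on every array, in shoot (green) and root (brown), by time at 4 °C; points are arrays, lines are the mean and SD of 4 arrays, and 24 h has 1 array. Hv1136B16_1 was up and Hv3085E19_1 down on every array, whereas Hv2115D22_1 stood at 5.11 ± 0.48 in root and 0.02 ± 1.06 in shoot at 3 h.

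Probes past the threshold in both shoot and root mostly changed in the same direction. At 6 h, 11636 probes did so and 639 went opposite ways, beside 19056 past the threshold in shoot and 19560 in root. Many others passed in only 1 tissue. At 6 h, 6737 probes rose in both tissues where independent lists of the same size would share 2698, and 4899 fell in both against 2041. Opposite changes were rarer than independent lists would give: 393 probes rose in shoot and fell in root against 2439, and 246 did the reverse against 2258. At 3 h, 4821 probes rose in both tissues and 2862 fell in both, and 291 went opposite ways. With median centring in place of loess the opposite changes numbered 604 at 3 h and 1206 at 6 h, beside 9828 and 13255 changes in the same direction. Because same-numbered shoot and root arrays are paired, the overlap at 6 h was also read in different replicates. With shoot from replicates 1 and 2 and root from replicates 3 and 4, 2924 probes rose in both against 760 for independent lists and 1506 fell in both against 322. The reverse choice gave 3999 against 1223 and 2042 against 605. Sets without effect that kept the pairs gave at most 154 shared rises and 64 shared falls at 6 h, and 556 and 296 at 3 h. The dye order was the same in all of these. Opposite changes of at least 2-fold in both tissues numbered 4 at 3 h and 10 at 6 h. Across probes, the mean log2 ratios of the 2 tissues correlated at 0.67 at either time. Probes are not independent replicates.

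**Figure D3:**
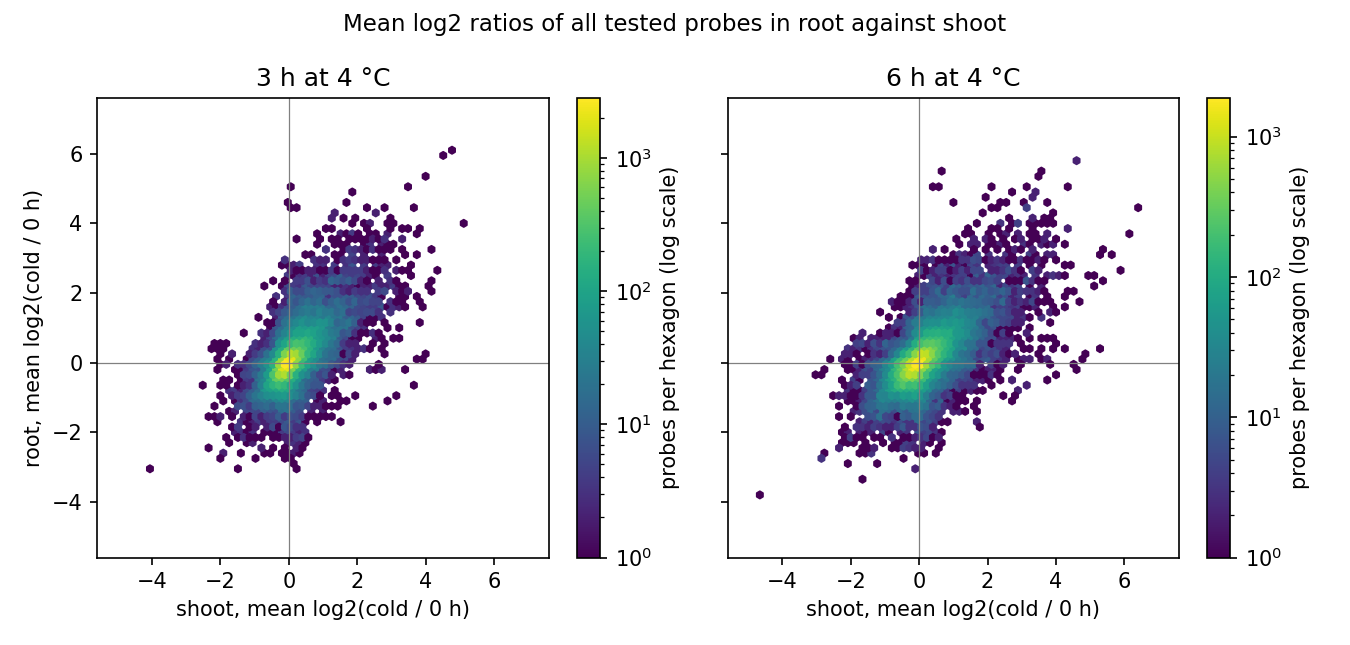
Mean log2 ratio of cold over 0 h in root (vertical) against shoot (horizontal) for all 39503 tested probes after 3 h (left) and 6 h (right), 4 arrays per group; colour gives the number of probes per hexagon on a log scale. The cloud follows the diagonal, with a correlation across probes of 0.67 in either panel, and a smaller set of probes lies along each axis.

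The size of the response nevertheless differed between the tissues for many probes. The contrast of the shoot and root ratios passed the threshold for 4336 probes at 3 h, of which 2225 were higher in shoot and 2111 higher in root. With the replicate block 7540 probes differed, and in a fit to the 8 arrays alone 2624. At least 2-fold differences numbered 1197, with 523 higher in shoot and 674 higher in root. This balance turned to 835 and 754 with the processed signals, to 736 and 688 with array weights and to 740 and 619 without root 3 h replicate 1. At 3 h, Hv1099B24_1 stood at 3.99 ± 0.39 in shoot and 0.12 ± 0.09 in root (SD, n = 4; limma adjusted p of the difference = 6.3e-08), and Hv1071A06_1 at 3.95 ± 0.34 and 0.27 ± 0.11 (SD, n = 4; limma adjusted p = 1.5e-08). In root the cold signal of Hv1099B24_1 was well above background on 1 of 4 arrays, so its root ratio is hardly measurable. That of Hv1071A06_1 was well above background on 3 of 4 cold and 2 of 4 untreated channels, so the size of its difference is uncertain. Root-preferential rises included Hv2115D22_1, at 5.11 ± 0.48 in root and 0.02 ± 1.06 in shoot (SD, n = 4; limma adjusted p = 0.00018), with the sequence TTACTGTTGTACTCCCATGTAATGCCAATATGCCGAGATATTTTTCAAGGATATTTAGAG. Hv2004D15_1 stood at 4.56 ± 0.47 in root (SD, n = 4; limma adjusted p of the difference = 8.0e-07). Its shoot signal was well above background on 1 of 4 cold and 0 of 4 untreated channels, so its ratio in shoot and the size of the difference are not measured.

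At 6 h, 7726 probes responded differently in shoot and root, 4155 of them with the higher ratio in shoot, and 1893 differed by at least 2-fold. The replicate block gave 11747, and the deposited ratios gave 3572 probes higher in shoot and 3671 higher in root. Hv1101N02_1 stood at 5.36 ± 0.22 in shoot and at a fitted 0.37 in root (SD, n = 4; limma adjusted p of the fitted difference = 3.4e-10). Hv3094L05_1 stood at 4.57 ± 0.31 and -0.18 ± 0.78 (SD, n = 4; limma adjusted p = 2.3e-06). The root signal of Hv1101N02_1 was well above background on 2 of 4 cold and 0 of 4 untreated channels, and that of Hv3094L05_1 on 1 of 4 channels of either kind, so the size of either difference is not measured. Hv2115D22_1 stood at 5.48 ± 1.06 in root and 0.72 ± 1.10 in shoot (SD, n = 4; limma adjusted p = 0.00016). Hv2004D15_2 stood at 5.05 ± 0.58 in root and at a fitted 0.43 in shoot (SD, n = 4; limma adjusted p of the fitted difference = 1.6e-07). In shoot, the untreated signal of Hv2004D15_2 was well above background on 0 of 4 arrays, so its shoot ratio and the size of the difference are not measured. Hv2004D15_2 overlaps in sequence with Hv2004D15_1, and Hv1101N02_1 begins with the bases that end Hv1071A06_1. The probes named at 3 h and at 6 h may therefore not stand for separate transcripts.

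After 24 h there was 1 array per tissue, with no replicate check. On the shoot array 4273 probes were at least 2-fold up and 2894 down, and on the root array 3316 were up and 2344 down. At 3 h and 6 h, single arrays held at most 1372 such falls in shoot and at most 1892 in root. The largest ratios in shoot were 7.43 for Hv1113P18_1 and 7.16 for Hv2050M07_1, and the lowest were -4.58 for Hv1096O19_1 and -4.50 for Hv3007F02_1. In replicate 1 at 6 h, the last 2 had stood at -0.72 and -0.99. In root the largest were 6.52 and 6.42 for the 2 probes of clone Hv2011N24, and the lowest were -4.23 for Hv2020E04_1 and -4.03 for Hv3022I17_1. Of the shoot probes named at 6 h, Hv1136B16_1 stood at 5.26, Hv3085E19_1 at -4.27 and Hv2106P13_2 at -3.55. Outside the rule for 24 h, Hv2030H21_2, named in shoot at 3 h, stood at -0.21 in shoot. Of the root probes named at 6 h, Hv2030H21_2 stood at 2.49, Hv2030H21_1 at 2.48, Hv3085E19_1 at -3.85 and Hv2050M16_1 at -1.30. With the processed signals the rises and falls at 24 h were nearly equal in number, at 4771 and 4634 in shoot and 3766 and 3786 in root.

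Probes chosen at 6 h in replicates 2 to 4 were followed through replicate 1, whose 3 arrays per tissue may share 1 untreated RNA. The 2759 shoot probes that rose at least 2-fold had medians of 1.14, 1.49 and 1.42 at 3 h, 6 h and 24 h, and 95.4% of them were above 0 at 24 h. The 717 that fell had medians of -0.83, -1.18 and -1.43. In root the 2848 that rose had medians of 1.41, 1.39 and 1.09, and the 1209 that fell had medians of -0.70, -0.96 and -0.87. The 2223 root probes chosen as risen at 3 h went from 1.54 at 3 h to 0.77 at 24 h, and 40.5% were still at least 2-fold up. The 1522 shoot probes chosen in the same way went from 1.51 to 1.30, and 61.8% were still at least 2-fold up. Those chosen as fallen at 3 h went from -1.39 to -1.38 in shoot (193 probes) and from -0.50 to -0.35 in root (896 probes). Probes that were within 0.5 of 0 on the log2 scale at 3 h and 6 h, both in the group means and in replicate 1, included 592 that were at least 2-fold up and 712 that were at least 2-fold down at 24 h in shoot. The root array held 447 and 428 such probes.

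More probes differed between the untreated tissues than between cold and 0 h in either tissue. Of 39503 probes, 29259 (74.1%) differed between untreated shoot and root, 10218 higher in shoot and 19041 higher in root, and with each array centred on its median tested probe the split was 10293 and 18817. That centring acts on each array and not on the differences between tissues. The median difference over all tested probes was 0.36 lower in shoot on the log2 scale, so small differences are relative to that shift. Whether the split of all calls reflects this shift was therefore not tested by the centring. At least 4-fold differences comprised 4629 probes higher in shoot and 3042 higher in root. Hv1089J16_2 was higher in shoot, with a log2 signal of 17.09 ± 0.38 in shoot and 6.92 ± 0.63 in root (SD, n = 4; limma adjusted p = 7.1e-09). Hv2031M03_1 was also higher in shoot, at 16.47 ± 0.36 (SD, n = 4; limma adjusted p = 6.2e-10). In root these probes were well above background on 5 and 2 of 8 arrays, so the root level lies near background, and neither the size of the difference nor the rank of these probes is measured. Hv2022H16_1 was at least 1149-fold higher in root, with 0 of 8 shoot arrays well above background (limma adjusted p = 2.7e-09). Hv2088P23_1 differed by -10.32 (7.12 ± 0.56 in shoot and 17.44 ± 0.29 in root, SD, n = 4; limma adjusted p = 2.9e-09).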

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

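The tests on background correction and normalization, on compression of the ratio scale, on the slide and on a shared untreated RNA were chosen after the results they bear on were seen. The test on dye bias and the other splits of the samples were written before.

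The following counts and probes passed a test of the difference in response between times or tissues itself, with limits for some probes given below. Between 6 h and 3 h, 577 probes differed in shoot and 125 in root. The named ones were, in shoot, Hv1092H07_2 (2.85 on the log2 scale), Hv1110O16_1 (2.83), Hv1100C09_1 (-2.12) and Hv2032H17_1 (-1.71), and in root Hv3135G05_1 (1.69), Hv1129B03_1 (1.56), Hv1100C09_1 (-2.16) and Hv3129N03_1 (-1.77). Between shoot and root, 4336 probes differed at 3 h, among them Hv1099B24_1 (3.87), Hv1071A06_1 (3.68), Hv2115D22_1 (-5.10) and Hv2004D15_1 (-4.54). At 6 h, 7726 differed, among them Hv1101N02_1 (4.99), Hv3094L05_1 (4.75), Hv2115D22_1 (-4.76) and Hv2004D15_2 (-4.62). Hv1101N02_1 shares bases with Hv1071A06_1, and Hv2004D15_2 with Hv2004D15_1, so these may not be separate transcripts. For Hv1092H07_2, Hv1110O16_1, Hv2004D15_1, Hv1101N02_1 and Hv2004D15_2, the untreated signal on 1 side of the contrast was not well above background on any of the 4 arrays. Their values are therefore fitted values and not measured sizes, and these ratios alone do not settle that the responses differ. The values of Hv1099B24_1 and Hv3094L05_1 are not measured sizes either, as their root signal was well above background on 1 of 4 arrays in either channel. That of Hv1071A06_1 is uncertain, with 3 of 4 cold and 2 of 4 untreated root channels well above background. With the processed signals Hv1092H07_2 came to 2.11 (adjusted p = 0.12, from 4.8e-05 to 0.12 over the alternatives) and Hv1110O16_1 to 2.23 (0.13, from 6.9e-05 to 0.13).

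Other splits of the samples cannot exclude chance in the choice of groups, because same-numbered samples are taken as paired. The real split gave 4336 and 7726 probes for the tissue contrasts at 3 h and 6 h, and 29259 for the untreated tissues. In each case it was the only 1 of the 35 splits to give as many, and the highest other gave 0. Every other split sets both tissues on each side, so the tissue difference enters its spread. Only 8 of these splits part every pair of same-numbered samples, which is too few for a share under 0.05, and among them too the highest other gave 0. For 6 h against 3 h, chance cannot be excluded over all 35 splits either. In shoot, 2 of the 35 splits gave 577 or more, the other giving 679. In root, 3 of the 35 gave 125 or more, with 3939 as the highest. That split set replicates 1 and 4 at both times against replicates 2 and 3, as did the shoot split with 679, so it points to a structure of the replicates. Among the 8 splits that part every pair, again too few for a share under 0.05, the real one gave the most in both tissues and the next gave 0, and the replicate block gave 1780 and 824. For the ratios against 0 h, 8 sign patterns are too few for a share under 0.05. The real pattern, 1 of 8, gave 12031, 19056, 16791 and 19560 probes for shoot 3 h, shoot 6 h, root 3 h and root 6 h, and the highest other gave 68, 0, 1 and 1.

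Some arrays lay far from the other 3 of their group by Dixon's criterion, which chance meets in about 1 of 20 groups (5 of 80 groups tested here). Shoot 3 h replicate 4 had 1526 spots with an outlier flag. Root 6 h replicate 4 had 4093 probes at least 2-fold up. In root 6 h replicate 1, 85.7% of probes were well above background in Cy3. Hv3129N03_1 stood at -0.31 in root 6 h replicate 2, and Hv1071A06_1 at 3.44 in shoot 3 h replicate 1.

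A first pattern is that 4196 probes rose and 2416 fell in all 4 comparisons with 0 h. Independent lists would share 112 and 48.8, and 8 sets without effect that kept the shared untreated RNA gave at most 93 and 26. No count expected for the list sizes of those sets is given, so they do not bound the part of the shared RNA. With 3 h read in replicates 1 and 2 and 6 h in replicates 3 and 4, the counts were 1411 and 356, and 1478 and 506 the other way round. A dye bias of the probe would be alike on every array. Of these probes, 40.4% differed in at least 1 of the 4 contrasts between times or tissues with the replicate block, against 35.04% of the other tested probes. This lies above the 5% set as the bound for a dye bias as the whole cause and below the 50% set for excluding it. A dye bias in part of the set stays open because no array was swapped, as does a response common to both tissues. Time of day, which differed between the channels in all 4 comparisons, was not tested and stays open too.

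A second pattern is that changes of at least 2-fold were mostly rises, from 72.7% in root at 6 h to 88.0% in shoot at 3 h. Under the processed signals, median centring and no background correction, the lowest share over the 4 comparisons was 65.2%. This lies above the bound set for arguing against the processing as the whole cause. In the deposited ratios without centring, which the rule did not cover, the lowest share was 59.7%, just below that bound. There, falls also outnumbered rises among calls of all sizes in all 4 comparisons. The processing as the whole cause is therefore not settled, and it sets part of the size. Compression of falling ratios is argued against by the spike-in controls, whose highest ratio lay 1.01 times as far from their mean as the lowest (median of 18 arrays). The probes' own 99th percentile lay 1.68 to 2.26 times as far from 0 as their 1st. A dye bias was not tested for this pattern and stays open, since no array was swapped. The difference in time of day between the channels was not tested either. A larger induction than repression of transcripts in the first hours of cold remains as a hypothesis found and tested on the same data.

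Another pattern is that same-numbered arrays of a tissue deviated together, with a median correlation of 0.70. The slide or scan as the whole cause is argued against by the pairs of different tissues on 1 slide, whose median was 0.28, and by root replicate 1, whose 3 h and 6 h arrays lay on different slides and correlated at 0.73. An untreated RNA used on both arrays of a replicate goes with a median correlation of 0.94 in Cy3, above the Cy5 value in 8 of 8 pairs. Seedlings grown and harvested together would give the same sign, and no biological explanation was tested.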

How the results depend on the processing

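The alternatives were fixed before the data were examined, except the centring of untreated arrays and the reading of the time course and of the tissue overlap in held-out replicates, which were chosen after. None of 473 tests of named probes under alternatives reversed a direction, and 446 stayed past the threshold (largest adjusted p = 0.21), with the left-out arrays entered once per probe and comparison at their highest p. Of the 27 that did not, 26 concerned 6 h against 3 h and 1 was Hv2052F11_1 in root at 3 h. Taken singly, 192 tests of the probes named for the cold comparisons with 1 array left out lost 16 calls, all for 6 h against 3 h, and reversed 0. The total counts for shoot 6 h, root 3 h, root 6 h, the untreated tissues and the 24 h arrays stayed within 1.5 times of those reported under each alternative run, and those for shoot 3 h and the tissue contrasts did too except as given here. The counts of falls moved further. Falls of at least 2-fold went from 232 to 514 with the processed signals and 656 in the deposited ratios for shoot 3 h, from 689 to 1371 and 1745 for shoot 6 h, from 736 to 1551 and 1805 for root 3 h, and from 1055 to 1969 and 2272 for root 6 h. All falls in shoot at 3 h went from 4670 to 7705 in the deposited ratios and 2282 in the fit to 4 arrays, and those in root at 3 h from 7982 to 4999 in the fit to 4 arrays. At 24 h the processed signals moved the falls from 2894 to 4634 in shoot and from 2344 to 3786 in root. In the tissue contrast at 3 h, probes at least 2-fold higher in shoot went from 523 to 835 with the processed signals and 828 with median centring, and at 6 h the probes lower in shoot went from 3571 to 5453 with the slide block. For shoot 3 h, the processed signals gave 3075 probes at 2-fold or more instead of 1937, and a fit to the 4 arrays alone gave 7620 instead of 12031. For the tissue contrast at 3 h (4336), the 8 arrays alone gave 2624, the replicate block 7540 and the slide as a random block 7594. At 6 h (7726), the replicate block gave 11747. For shoot 6 h against 3 h (577, and 181 at 2-fold or more), scaling between arrays gave 126 and 52, the 8 arrays alone 181 and 113, array weights 973 (at 2-fold or more 63 lower instead of 24), the replicate block 1780 and 332, and the slide block 2122 and 360, and at 2-fold or more 48 were lower with the processed signals and in the deposited ratios. For root 6 h against 3 h (125 and 33), an offset of 10 gave 50, the processed signals 40 and 19, the deposited ratios 41 and 18, scaling 42 and 16, the 8 arrays alone 0 and 0, array weights 471 and 62, the replicate block 824 and 91, and the slide block 854 and 87. Fits to 4 or 8 arrays have fewer residual degrees of freedom, and the cause of the other differences was not tested. The replicate block moved no other total by more than 1.5 times and ended no call of a named probe.

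Leaving out each array in turn gave, in all and at 2-fold or more, 8376 to 11817 and 1727 to 2268 for shoot 3 h, 15261 to 17355 and 3313 to 3776 for shoot 6 h, 13234 to 14653 and 2881 to 3304 for root 3 h, 16129 to 17463 and 3499 to 4087 for root 6 h, 179 to 593 and 81 to 192 for shoot 6 h against 3 h, 11 to 211 and 3 to 57 for root 6 h against 3 h, 2892 to 4159 and 976 to 1359 for the tissue contrast at 3 h, 5472 to 7046 and 1636 to 2040 at 6 h, and 27689 to 28441 and 15693 to 16242 for the untreated tissues. The opposite changes in shoot and root rose from 291 to 604 at 3 h and from 639 to 1206 at 6 h with median centring in place of loess. The tests of gene lists and their alternatives were not run, because no list matched a name. The 24 h arrays have no replicate, and between 82.0% and 89.1% of probes were well above background in Cy3, which limits ratios of dim probes.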

Other observations

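The hypotheses on tissue-preferential transcripts were written before their result was seen, and the protein motifs were chosen after the clone names were found to match no gene list, before any signal was examined.

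Probe Hv2121F15_1, singled out after its values were seen, has 60 bases that encode the lysine-rich K segment that defines dehydrins, proteins that accumulate in dehydrated and cold-treated plants. It passed the threshold as a rise in all 4 comparisons with 0 h, in the fit whose spread is shared by shoot and root arrays. The root replicates spread more widely than those of shoot, so the root calls lean on that shared spread. The alternatives were not read for this probe. Its log2 ratio was 1.21 ± 0.46 in shoot at 3 h (SD, n = 4; limma adjusted p = 0.032), 1.98 ± 0.34 in shoot at 6 h (SD, n = 4; limma adjusted p = 0.00089), 1.17 ± 1.27 in root at 3 h (SD, n = 4; limma adjusted p = 0.028) and 1.35 ± 1.03 in root at 6 h (SD, n = 4; limma adjusted p = 0.011). The single 24 h arrays gave 3.14 in shoot and 2.69 in root. The untreated tissues differed by 0.03 (adjusted p = 0.96). The motif was found by sequence alone, in 1 probe, and the files give the probe no name. Over all 50 motif classes searched, 27 matches lay on the forward strand and 20 on the reverse, of which 7 and 17 belonged to the fatty acid desaturase box, a class that was not kept. How often a match in a kept class arises by chance was not tested. The other kept classes were Aux/IAA domain, EF-hand loop, leucine-rich repeat, RING-H2 finger, histones H2A, H2B and H3, tubulin and the thioredoxin active site. Of their 10 tested probes, 3 rose and 1 fell in shoot at 3 h, 5 rose and 2 fell in shoot at 6 h, 3 rose and 2 fell in root at 3 h, and 4 rose and 1 fell in root at 6 h.

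Cold might have lowered the transcripts that mark each tissue. Preference was taken from 3 untreated replicates (at least 4-fold, past the threshold), and the response was read in the replicate left out. At 6 h the median log2 ratio of shoot-preferential probes in shoot differed from that of other probes by -0.049 ± 0.14 (mean and SD of 4 held-out replicates; exact sign-flip p = 1). Replicate 4 carried this mean, at -0.26, and the others stood at 0.0032, 0.056 and 0.0016. The mean lay above -0.1, which the rule set beforehand counted against the hypothesis. A condition on the spread, which that rule did not hold, was also applied. The mean lay above the bound by less than its SD, so the hypothesis is left open for shoot. Root-preferential probes in root differed by 0.13 ± 0.04 at 6 h (exact sign-flip p = 0.125, the smallest that 4 replicates allow), which argues against a lowering in root. The shift was not particular to root. With no replicate held out, root-preferential probes had a median of 0.13 in shoot at 6 h, against 0.012 for other probes. In shoot, 17.8% of shoot-preferential probes fell at 3 h against 11.8% of other probes, and 20.2% against 23.5% at 6 h. The cause of these shifts was not tested. At 3 h the shoot difference was -0.15 ± 0.17 (exact sign-flip p = 0.25), between -0.37 in replicate 1 and 0.01 in replicate 2, and the root difference was 0.11 ± 0.02 (exact sign-flip p = 0.125), above 0 in 4 of 4 replicates.

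Array controls differed in level between arrays. The mean log2 ratio of the 10 spike-in controls, relative to the median probe, ranged from -0.71 to 0.89 over the 18 arrays. Root 6 h replicate 4 and shoot 3 h replicate 4 had the lowest values, at -0.71 and -0.63. Base composition of the probes accounted for at most 0.19% of the variance of the log2 ratios in the 4 comparisons with 0 h. Of the 2980 probes left out as dim, 68 were well above background in the cold channel of the 24 h shoot array and 72 in its untreated channel, and 55 and 65 in root.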
